A study of Mus musculus with 2 samples.

How the data were processed

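Single-cell RNA-seq was measured with the Chromium 3' method in 2 mouse libraries, 1 per group: EPS-blastoids, the blastocyst-like structures that extended pluripotent stem (EPS) cells form in microwells, and natural blastocysts as the control. Per the labels' protocols, about 500 blastoids were picked, and about 4800 blastoid cells and 1000 blastocyst cells were loaded. Both were dissociated with the same enzyme mix, and both libraries were pooled on 1 sequencer. The blastoid label gives the sex as male and the blastocyst label as pooled male and female. No label gives the strain of the EPS cells. With 1 library per group, the structure, its strain, stage and culture and the library itself cannot be separated.

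The deposited matrices hold UMI counts per gene and barcode that the authors made with Cell Ranger 3.0.2, per the file headers, on the mm10 build, per the submitters' processing notes. The release of the annotation is not given. Each matrix lists 31053 genes and 6794880 barcodes and was not filtered for cells: 145763691 UMIs lie in the blastoid library and 20255613 in the blastocyst library. No cell annotation was used here: the cell classes were rebuilt, and they can differ from those of the study. Gene positions are from GENCODE M21 on GRCm38, the same assembly as mm10.

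Cells were called by a rule written before the data were examined. A barcode counted as a cell at 10% or more of the 99th percentile of UMIs over as many barcodes as cells were loaded, which is 11106 UMIs in the blastoid library and 16226 in the blastocyst library. This called 2378 and 165 barcodes, which is 49.5% and 16.5% of the numbers loaded. Barcodes with over 15% of UMIs from mitochondrial genes (372 and 30) or under 1000 genes (1 and 0) were left out. Scrublet, run in scanpy 1.11.5 at an expected 0.8% per 1000 cells, marked 13 and 9 doublets, which were removed. Its automatic threshold lay near 0 in the blastocyst library, so those 9 calls carry little meaning. The kept cells were 1993 and 126, with a median of 53619 and 111280 UMIs per cell.

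Each library was clustered by itself. Counts were scaled to 10000 per cell and logged, 2000 variable genes were scaled to a maximum of 10, and 30 principal components and 15 neighbours gave Leiden clusters at resolution 1. Marker lists for 12 classes were fixed before the data were examined. The rule that turns markers into names was not, and it was changed after its outcome was seen. A first rule, on mean marker levels, left trophectoderm-like cells and part of the endoderm-like cells without a name. A later rule asked for 40% of a class's markers to be high, and it named a cluster of low UMI totals (75 cells) formative and left a cluster led by T and Fgf8 (281 cells) unnamed. The rule used here was set so that the former stayed unnamed and the latter was called streak-like. A marker was high in a cluster at 0.5 or more of its highest cluster level, among markers that reached 20 CPM. A name needed 3 high markers, 33% or more of those detected, and either a lead of 2 high markers over the next class or 2 of its markers, more than of any other class, among the 10 leading genes. No name was given where another class had more markers among those genes. This last limit left 148 blastoid cells unnamed, with 4 of 7 formative markers high but 0 of them leading against 3 of another class. The streak-like share depends on this choice: it was 22.2% here and 8.08% at 40%. A cluster with a median UMI count under 1/3 of its library's and none of the markers leading was to stay unnamed.

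UMI counts were summed per library and class and expressed as CPM over all genes. Ratios are blastoid over blastocyst or the inverse, as worded, with exact conditional 95% intervals for 2 Poisson counts. Levels carry exact Poisson and shares exact Clopper-Pearson 95% intervals. All of them cover counting error only, and cover neither cells nor structures as replicates. A count of 0 was set to 3 UMIs and the ratio given as a bound. No test between the groups was possible, no p-value was computed and no changed genes were counted over the genome. A gene was called at least 2-fold higher or lower when its ratio reached 2 with an interval that excluded 1, among genes with 10 or more UMIs. Classes were compared where both libraries held 20 cells of them, and trophectoderm-like cells, with 8 in the blastocyst library, are described under a minimum of 5 added after seeing the data.

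For 28 gene lists fixed before the data were examined, the median log2 ratio (1 CPM added to each level) was set among 10000 random lists of the same size, matched on mean expression in 20 bins. A second median was taken over plain ratios with counts of 0 set to 3. The percentile describes these libraries and is no test of the conditions. Spearman correlations between class sums are across genes, which are not replicates. Genes were named by a rule fixed in advance. It takes, per class, the 8 highest and 8 lowest ratios among genes at 100 CPM or more with 50 UMIs in the higher library, leaving out mitochondrial genes, ribosomal protein genes, sex-linked list genes, pseudogenes and unnamed transcripts. It adds up to 4 members of each list by level or by size of ratio, and the 17 lineage regulators. Names outside the rule are said to be so.

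Shares of cells with a UMI were computed after thinning each cell to 29500 UMIs, which left out 204 blastoid and 7 blastocyst cells. Both libraries were also clustered together, without correction and after anchor integration in Seurat 5.3.0 under R 4.3.3. A cluster was called mixed when each library held 0.5 or more of its expected share, a definition set after seeing the data. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9. Alternatives covered the calling threshold, gene minimum, mitochondrial limit, doublets, resolution, variable genes, joint clustering, integration, scaling, pseudocount, expression filter and thinning. Further ones were added after seeing the data: doublets by expected share, 1 EPI-like cluster, the cell minimum for trophectoderm-like cells, thinned joint clustering and 3 naming settings. The tolerances of these comparisons (0.58 in log2, 0.05 in a correlation, 1.5 times in a count) and the choice of main lists (percentile under 2.5 or over 97.5) were also set after seeing the data.

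The size rule and the list percentile were tested on simulated data drawn from the sums of all kept cells over 16199 genes. All 100 genes changed 3-fold and all 100 changed 4-fold were recovered, and 88 of 15999 unchanged genes passed the size rule. The changed genes were drawn above a minimum level, with counting error only. Class sums are smaller, down to 757328 UMIs in TE-like blastocyst cells, so this recovery does not carry over to weak genes there. The interval held the true ratio for 95.3% of unchanged genes. Lists of 12 raised, lowered and unchanged genes lay at percentiles 100, 0 and 3.8. Naming gave 100% of 140 simulated blastocyst cells their true class. That simulation raised all naming markers of a class together, with counting error only, so it could hardly fail. It held EPI-like, PrE-like and TE-like cells only, and no streak-like, unnamed or mixed states. It therefore does not show how well the rule names real cells.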

Results

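The series holds single-cell transcriptomes of EPS-blastoids and of natural blastocysts, 1 library of each, set up to ask how alike the cells of both are. EPS-blastoids are blastocyst-like aggregates grown from extended pluripotent stem (EPS) cells, a cell state described as able to enter embryonic and extraembryonic lineages. They formed in a medium with FGF4, heparin, BMP4, a GSK3 inhibitor that turns on WNT signalling, and an inhibitor of activin and TGF-beta receptors. The blastocysts were flushed from ICR females 3.5 days after the plug and then cultured. The kept cells were 1993 from blastoids, with 11191 to 170245 UMIs each, and 126 from blastocysts, with 16461 to 196684 UMIs each. The median depth was 53619 UMIs and 6273 genes per blastoid cell, and 111280 UMIs and 7878.5 genes per blastocyst cell. Mitochondrial transcripts made up a median of 6.33% of UMIs in blastoid cells and 10.3% in blastocyst cells. A count of 0 over all kept cells allows up to 0.0268 CPM in the blastoid library and 0.221 CPM in the blastocyst library. No difference between the groups has a replicate check, and all intervals cover counting error only.

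The first question was which of the 3 blastocyst lineages, trophectoderm (TE), epiblast (EPI) and primitive endoderm (PrE), each library held. In both libraries clusters were named TE-like, EPI-like and PrE-like by their markers, which does not show that the cells are of that lineage. The blastoid library also held cells with primitive streak genes and many cells that no marker list named. In blastoids, 23.7% of cells (21.9 to 25.7%, exact binomial 95% interval) were PrE-like, 22.2% (20.4 to 24.1%) streak- or mesoderm-like, 6.72% (5.66 to 7.91%) TE-like and 6.17% (5.16 to 7.32%) EPI-like. In blastocysts, 69.0% (60.2 to 77.0%) were EPI-like, 24.6% (17.4 to 33.1%) PrE-like and 6.35% (2.78 to 12.1%, 8 cells) TE-like. The unnamed share was 41.2% (39.0 to 43.4%) in blastoids and 0 of 126 cells in blastocysts, which allows up to 2.38%.

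The blastoid PrE-like class joined a cluster led by the basement membrane genes Lama1 and Col4a1 and a cluster led by Apob, Ttr and Apoa1, which encode secreted proteins made by visceral endoderm. The streak-like class joined a cluster led by Rspo3, Fgf8 and Mesp1 and a cluster led by Igfbp3, T and Vim. The TE-like cluster was led by Rhox9, Cdkn1c and Gata2, and the EPI-like cluster by Mylpf, Trh and Klf2. Of the unnamed blastoid clusters, 1 was led by Pim2, Tdgf1, Utf1 and Pou5f1, 1 by Ptn, Nkx1-2, Gbx2 and Wnt8a, 1 by Gap43, Ifitm1 and Wnt6, 1 by histone genes, 1 by Zscan4d and Dppa3, and 1 of low depth by Gm26917 and Gm42418. In blastocysts 4 clusters were EPI-like, 1 was PrE-like, led by Foxq1 and Lama1, and 1 was TE-like, led by Krt18, Dppa1 and Gata3. The genes that define the classes differ between the libraries, so the shares are not set against each other. The streak-like share rests on a naming threshold chosen after the clusters were seen and was 8.08% under a stricter one, and the blastocyst TE-like share was 23.8% at a lower clustering resolution and 0% at a mitochondrial limit of 10%. The blastoid TE-like share was 10.5% at the lower resolution and 3.61% at a higher one. The unnamed blastocyst share was 17.0% at a calling threshold of 5%, 14.3% at the higher resolution and 16.7% after anchor integration, beyond what counting error at 0 of 126 allows. Over the settings tried, the EPI-like blastoid share lay between 3.79% and 8.28% and the PrE-like blastocyst share went down to 11.1%.

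**Figure D1:**
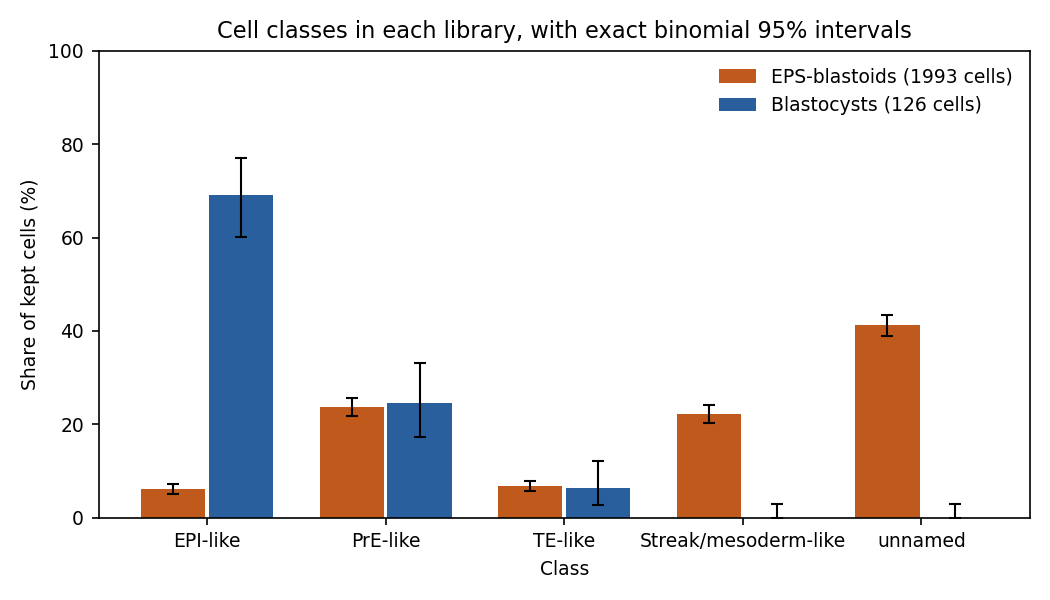
Share of kept cells in each class, as percent, for the blastoid library (1993 cells) and the blastocyst library (126 cells), with exact binomial 95% intervals as error bars. EPI-like cells made up 69.0% of the blastocyst library, and unnamed cells 41.2% of the blastoid library.

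The streak-like blastoid cells held T together with Cdx2, Pou5f1 and the keratin transcript Krt18. In the larger of their clusters (281 cells) as many TE markers were high (3 of 11) as streak markers (3 of 8). T, the brachyury gene of the primitive streak, had a UMI in 95.6% of streak-like cells (93.2 to 97.4%) after thinning and in 97.51% before, against 6.44% of PrE-like blastoid cells, a class that should lack it. T is among the markers that named the class, so its share follows in part from the naming. Cdx2 (ENSMUSG00000029646, chromosome 5, 147300805 to 147307270 on GRCm38), a regulator of trophectoderm and later of the posterior embryo, stood at 144 CPM (139 to 149) there, and Mixl1, a streak gene, at 29.0 CPM (26.9 to 31.3). A Mixl1 UMI was found in 30.3% of thinned streak-like cells and a UMI of Mesp1, another streak marker, in 21.1%. Pou5f1, the pluripotency factor OCT4, stood at 282 CPM in the same cells. T and Krt18 were found together in 336 of 413 thinned streak-like cells (81.4%, 77.3 to 85.0%), against 36.2% of unnamed and 6.44% of PrE-like blastoid cells. Krt18 alone had a UMI in 83.8% of thinned streak-like, 81.4% of unnamed and 100% of PrE-like blastoid cells. The difference in these joint shares thus follows mainly from T, which helped name the class. Cdx2 and Pou5f1 were found together in 344 of 413 thinned streak-like cells (83.3%, 79.3 to 86.8%) and in 8 of 8 TE-like blastocyst cells. This held for 53.7% of unnamed and 12.3% of EPI-like blastoid cells. The unnamed blastoid cells held Pou5f1 at 493 CPM and Cdx2 at 57.3 CPM, and T had a UMI in 43.9% of them. Median depths before thinning were 49958 UMIs in streak-like, 50891 in unnamed and 61581 in PrE-like blastoid cells.

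The next question was whether blastoid cells lie with blastocyst cells. Clustered together, none of 14 clusters was mixed: 0 of 1993 blastoid and 0 of 126 blastocyst cells lay in mixed clusters, which allows up to 0.151% and 2.38%. After anchor integration, which aligns libraries on pairs of similar cells and so draws them together by construction, 4 of 12 clusters were mixed. These held 41.9% of blastoid cells (39.7 to 44.1%) and 59.5% of blastocyst cells (50.4 to 68.2%). All 123 EPI-like blastoid cells lay in them, as did 95.5% of TE-like, 72.4% of streak-like and 53.9% of PrE-like blastoid cells, but 1.10% of unnamed ones. Of blastocyst cells, 96.8% of PrE-like, 42.5% of EPI-like and all 8 TE-like cells lay in them, but not always with their namesakes. Of 31 PrE-like blastocyst cells 16 (51.6%, 33.1 to 69.8%) lay in the cluster with PrE-like blastoid cells and 14 (45.2%, 27.3 to 64.0%) in the one with streak-like blastoid cells. The 1.10% for unnamed blastoid cells depends on the definition of mixed, set after seeing the data. In clusters not called mixed, 279 unnamed cells lay with 8 EPI-like blastocyst cells, 173 with 5 and 22 with 33.

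Class sums gave an order of likeness across 17156 genes. EPI-like blastoid cells came closest to EPI-like blastocyst cells (Spearman correlation 0.884, against 0.874 with PrE-like and 0.798 with TE-like ones). PrE-like blastoid cells came closest to PrE-like blastocyst cells (0.862, against 0.824 with EPI-like). TE-like blastoid cells did not come closest to their namesake: 0.808 with TE-like, 0.852 with PrE-like and 0.840 with EPI-like blastocyst cells. The order differed when seen from the blastocyst classes. To PrE-like blastocyst cells, EPI-like blastoid cells were closer (0.874) than PrE-like ones (0.862). To TE-like blastocyst cells, TE-like blastoid cells were the closest blastoid class, ahead of EPI-like and PrE-like (both 0.798), unnamed (0.785) and streak-like cells (0.772). Streak-like cells lay at 0.838 to PrE-like and 0.824 to EPI-like blastocyst cells. The TE-like blastocyst sum rests on 8 cells and 757328 UMIs, against 9491661 UMIs for EPI-like, and a shallow sum lowers a rank correlation.

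EPI-like cells were compared first. Pou5f1 and Sox2 were near in level, Nanog and Fgf4 were lower in blastoids, and part of the EPI-like blastocyst cells also held primitive endoderm genes at levels that EPI-like blastoid cells did not reach. Pou5f1 stood at 820 CPM in blastoid and 822 in blastocyst EPI-like cells (ratio 0.998, 0.965 to 1.03), and Sox2, its partner, at 171 and 210. Nanog (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633 on GRCm38), which keeps epiblast identity, was 2.22-fold lower in blastoids (2.07 to 2.37), and Fgf4, the epiblast's signal to its neighbours, 3.37-fold lower at 31.2 against 105 CPM. Gata6 (ENSMUSG00000005836, chromosome 18, 11052064 to 11085635), a driver of primitive endoderm, was 168-fold lower in blastoids (81.5 to 420), at 0.869 against 146 CPM. Within the blastocysts, Gata6 stood at 211 and 312 CPM in EPI-like clusters 0 and 2 but at 16.9 and 26.4 CPM in clusters 1 and 3. Sox17 and Pdgfra, which also mark primitive endoderm, stood at 2.23 and 0.993 CPM in blastoids against 21.2 and 40.8 in blastocysts. T stood at 16.4 CPM in blastoid EPI-like cells, against 3.20 in PrE-like blastoid cells, and at 0 in EPI-like blastocyst cells, so it was at least 51.9-fold higher. The classes were cluster 11 of the blastoids (8054417 UMIs) and clusters 0 to 3 of the blastocysts. Against the blastocyst cluster with the most EPI-like markers alone (28 cells, chosen after seeing the data), the log2 ratio of Gata6 was -3.26 in place of -6.30, and Sox17 turned from -2.78 to 1.69 and Gata4 from -0.86 to 0.10.

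**Figure D2:**
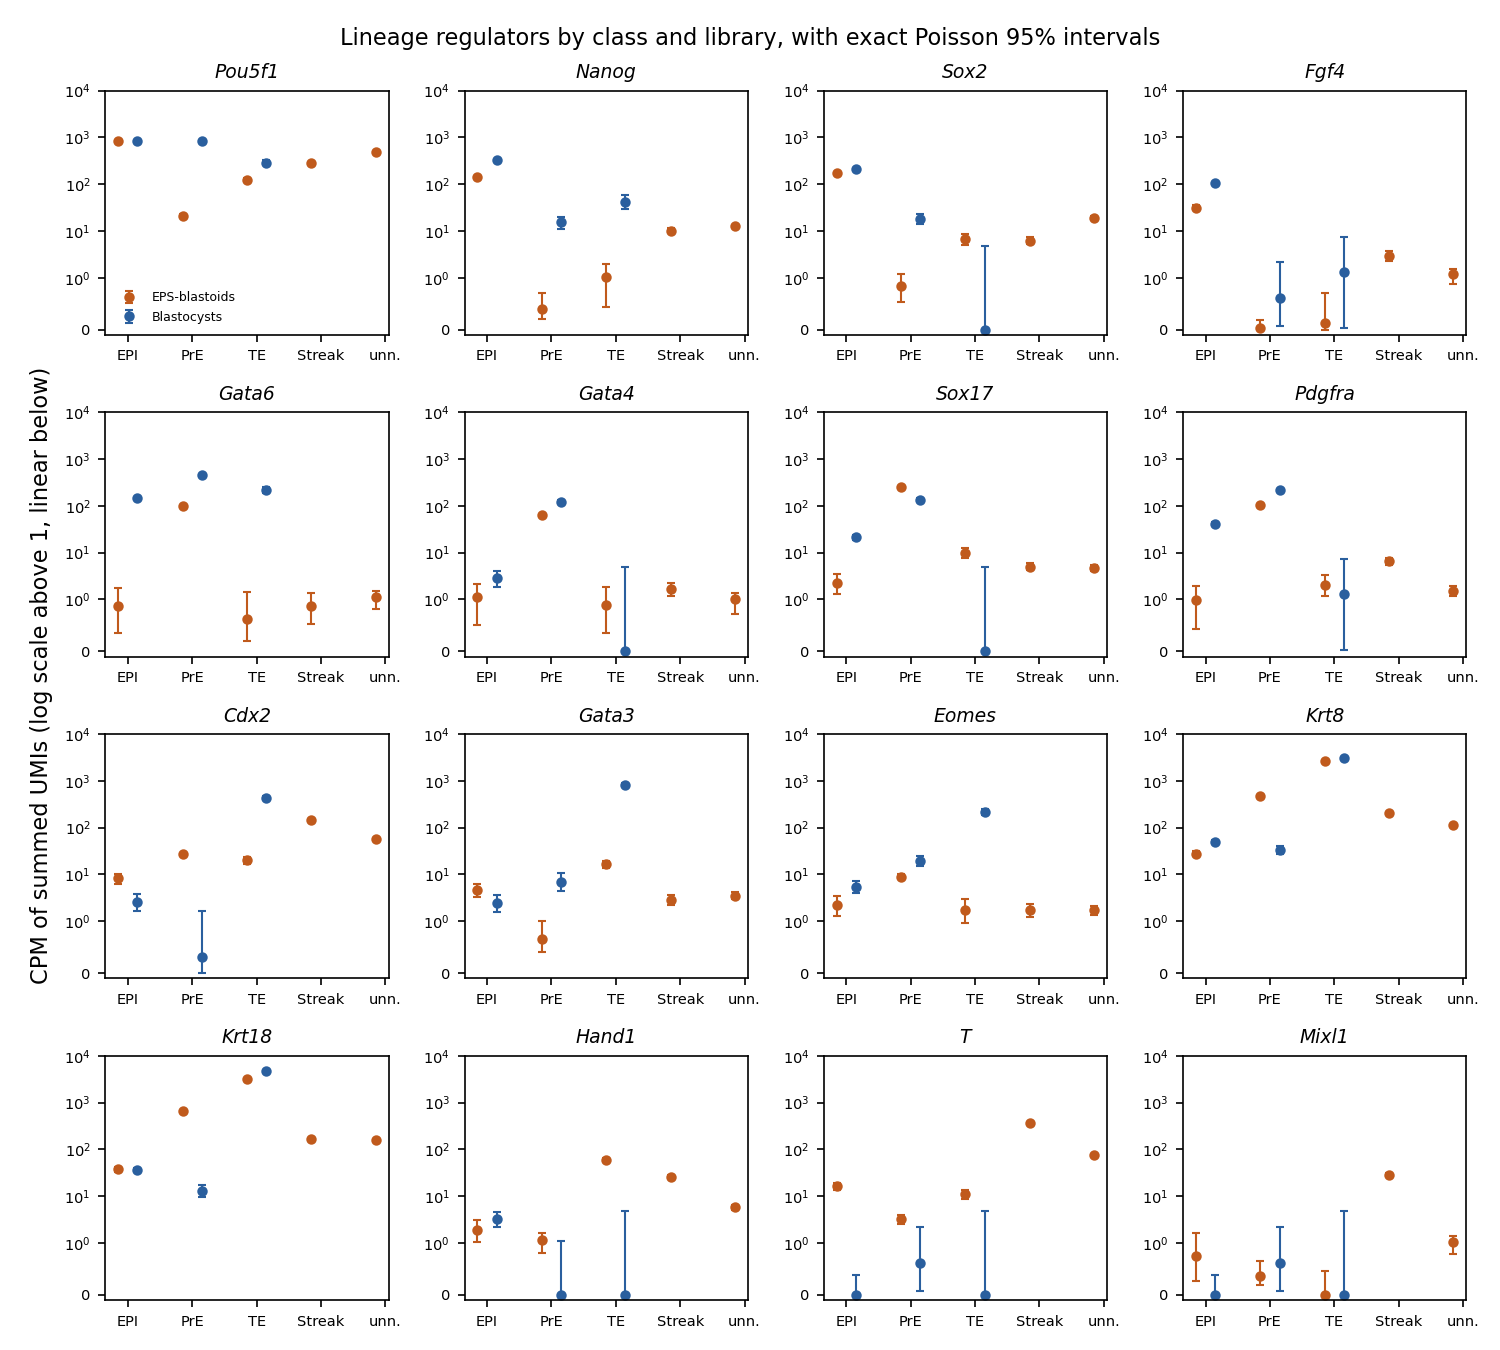
CPM of 16 lineage regulators in each class of the blastoid and blastocyst libraries, on an axis that is linear near 0 and logarithmic above, with exact Poisson 95% intervals as error bars (unn., unnamed cells; a class absent from a library has no point). Gata6 stood at 146 CPM in EPI-like blastocyst cells and 0.869 CPM in EPI-like blastoid cells.

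Joint detection of Nanog and Gata6 in single cells, seen in the inner cell mass before its lineages part, differed likewise. It held for 43 of 82 thinned EPI-like blastocyst cells (52.4%, 41.1 to 63.6%) and 12 of 29 PrE-like ones (41.4%), but for 1 of 114 EPI-like blastoid cells (0.877%, 0.0222 to 4.79%). The 52.4% depends on the mix of clusters, as it was 15 of 18 and 19 of 21 cells in EPI-like clusters 0 and 2 but 4 of 27 (14.8%, 4.19 to 33.7%) and 5 of 16 in clusters 1 and 3. Gata6 alone had a UMI in 53.7% of thinned EPI-like blastocyst cells (42.3 to 64.7%) and 69.0% before thinning, against 0.877% and 5.69% of EPI-like blastoid cells. Krt18, the transcript of a TE keratin, had a UMI in 6.90% of thinned PrE-like blastocyst cells and 54.8% before thinning, and in 36.6% (26.2 to 48.0%) of thinned EPI-like ones and 60.9% before. In cluster 1 Krt18 was found in 7 of 27 cells, so the Gata6 share there is not above that of Krt18. In cluster 3 the 2 genes were near, with Krt18 in 4 of 16 cells and Gata6 in 5. In cluster 0 the intervals overlapped, with Krt18 in 10 of 18 (30.8 to 78.5%) and Gata6 in 15 (58.6 to 96.4%). They parted in cluster 2, with Krt18 in 9 of 21 (21.8 to 66.0%) and Gata6 in 20 (76.2 to 99.9%). In blastocyst barcodes under 100 UMIs, too small to be cells, Krt18 stood at 523 CPM and Gata6 at 176. Krt18 is thus a high mark to set Gata6 against. A Gata6 share that does not pass it does not show that Gata6 came from outside the cells. Median depths were 113297 UMIs in EPI-like and 108418 in PrE-like blastocyst cells and 64962 in EPI-like blastoid cells.

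Naive pluripotency genes were mostly lower and formative ones higher in EPI-like blastoid cells. Of 12 measured naive genes, 8 were at least 2-fold lower and 1 at least 2-fold higher (median log2 ratio -1.46, percentile 0; -1.53 with undetected members at the floor). Tfcp2l1, a core naive factor, stood at 17.8 against 229 CPM (12.9-fold lower, 10.9 to 15.4) and Klf4 at 27.6 against 264. Klf2 was not lower, at 435 against 328 CPM, and the member at least 2-fold higher was Nr0b1 (8.92-fold). All 9 measured formative and primed genes were at least 2-fold higher (median 1.69, percentile 100; 1.96 with undetected members at the floor). Nodal, a signal of the postimplantation epiblast, was 10.3-fold higher (8.10 to 13.3), Dnmt3b, a de novo DNA methyltransferase, 2.91-fold, and Pou3f1 9.49-fold. Lef1, a WNT transcription factor, stood at 25.9 CPM in blastoids and 0 in blastocysts (at least 82.1-fold higher). Over all 13174 genes compared, the median log2 ratio was -0.16 in EPI-like cells, and list medians read relative to it.

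Most WNT and BMP targets were higher in EPI-like blastoid cells, while FGF and ERK targets and Nodal and activin targets went both ways. Of 12 measured WNT targets 9 were at least 2-fold higher and 2 lower (median log2 2.19, percentile 100; 3.25 at the floor). Ccnd1, which drives entry into the cell cycle, was 6.70-fold higher, Axin2, a feedback inhibitor of WNT, 2.31-fold, and Sp5 at least 63.6-fold. Of 10 BMP targets 6 were higher and 0 lower (1.15, percentile 99.9; 1.48 at the floor). Among them Id1, an inhibitor of bHLH factors, stood at 148 against 3.48 CPM (42.7-fold) and Id3 at 424 against 149. Of 10 FGF and ERK targets 5 were higher and 2 lower (1.06, percentile 99.97; 1.12 at the floor): Egr1 was 43.0-fold and Dusp6, a phosphatase of ERK, 3.14-fold higher, Etv5 stood at 110 CPM in both, and Spry2 was 2.87-fold lower. Egr1 is also in the list of immediate early genes, which dissociation can turn on. Of 7 Nodal and activin targets, 4 were higher and 2 lower (0.89, percentile 99.7; 1.09 at the floor), with Lefty2, a Nodal antagonist, at 0.372 against 27.2 CPM and Tdgf1, its co-receptor, at 292 against 599. The Nodal median turned to -0.093 with the libraries clustered together, -0.41 with thinned cells and -0.24 with weakly expressed genes left out. The FGF and ERK median was 0.35 with the libraries clustered together and 0.31 against the blastocyst cluster with the most EPI-like markers alone. The WNT and BMP medians were smaller with 10 CPM added, as given below.

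Energy and sterol genes also stood apart in EPI-like cells. Of 14 glycolysis genes 10 were at least 2-fold higher in blastoids and 1 lower (median log2 2.15, percentile 100). Ldha, which makes lactate, stood at 1306 against 130 CPM, Gapdh at 4278 against 1432, and the glucose transporter Slc2a3 at 303 against 16.2. Eno1 stood at 1277 against 32.0 CPM, a value that reads shared with its near-identical copy Eno1b leave uncertain. Genes of the respiratory chain encoded in mitochondrial DNA went the other way: 7 of 13 were at least 2-fold lower in blastoids and 0 higher (-0.99, percentile 0.03), among them mt-Nd3 at 598 against 3780 CPM. The nuclear respiratory chain genes stayed near level, with 1 of 16 higher and 0 lower (0.11, percentile 59.5). Of 17 cholesterol synthesis genes 11 were higher and 0 lower (1.21, percentile 100), with Cyp51, a lanosterol demethylase, 6.12-fold higher. Hypoxia genes were split, 4 of 11 higher and 4 lower (0.46, percentile 98.2), with Pdk1, a brake on pyruvate entry into mitochondria, 16.6-fold higher and Egln1 3.07-fold lower. Their median turned to -0.42 with weakly expressed genes left out.

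Imprinted genes and p53 targets were higher and matrix genes lower in EPI-like blastoid cells. Of 21 imprinted genes 16 were at least 2-fold higher and 2 lower (median log2 2.29, percentile 100; 2.76 at the floor). This median was smaller with 10 CPM added and against the blastocyst cluster with the most EPI-like markers alone, as given below. Peg10, needed in the placenta, stood at 99.6 CPM against 0 (at least 315-fold higher), the noncoding RNA Meg3 at 301 against 47.8, and Phlda2, which restrains placental growth, at 198 against 11.1. Of 12 p53 targets 9 were higher and 1 lower (1.52, percentile 100), with Phlda3 7.63-fold and the cell cycle inhibitor Cdkn1a 3.81-fold higher. Of 14 immediate early genes, which dissociation can turn on, 6 were higher and 0 lower (0.68, percentile 99.6; 1.15 at the floor). Of 12 matrix genes 9 were lower and 3 higher (-1.93, percentile 0): Spp1, osteopontin, stood at 75.6 against 1067 CPM and Nid1, a basement membrane linker, at 2.73 against 111, while Col18a1 stood at 89.1 against 0.421. Junction and blastocoel transport genes were lower in 7 of 19 and higher in 1 (-0.86, percentile 0.23), with the water channel Aqp3 6.17-fold lower and Cldn6 16.0-fold higher. Among DNA methylation genes, which parted (2 of 9 higher, 3 lower; -0.54, percentile 10.2), the demethylating enzymes Tet1 and Tet2 stood at 77.2 and 14.4 CPM against 352 and 149.

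The largest single ratios in EPI-like cells are given among genes that the naming rule admits, at 100 CPM or more in the higher library. They were led by Bex1 (ENSMUSG00000050071, chromosome X, 136213972 to 136215513), an X-linked gene at 728 CPM in blastoids against 2.63 in blastocysts (276-fold, 187 to 427). It was followed by Ifitm1 (160-fold), Ldhb, the heart form of lactate dehydrogenase (128-fold), the retinol-binding Rbp1 (127-fold), Bex4 (101-fold), Rhox5 (79.6-fold), Pclaf (70.4-fold) and Pla2g1b (50.3-fold). At the other end Khdc3 (ENSMUSG00000092622, chromosome 9, 73101836 to 73104438), part of the maternal complex of the egg and early embryo, stood at 1.37 CPM in blastoids against 1720 in blastocysts. Bhmt, which remethylates homocysteine, stood at 0.248 against 834 CPM (2 UMIs in blastoids), Pramel6 at 0.124 against 210 and Olfr1459 at 0.124 against 532, each on 1 UMI in blastoids. Sycn, Pramel4, Trim43a and Timd2 had no UMI in blastoids and were at least 460-, 418-, 345- and 343-fold lower. Bhmt, Pramel4 and Trim43a were among the leading genes of blastocyst cluster 2 (23 of the 87 EPI-like cells), so their place here follows in part from that cluster. Bex, Rhox, Pramel, Trim43 and olfactory receptor genes have close copies, so their counts are uncertain.

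**Figure D3:**
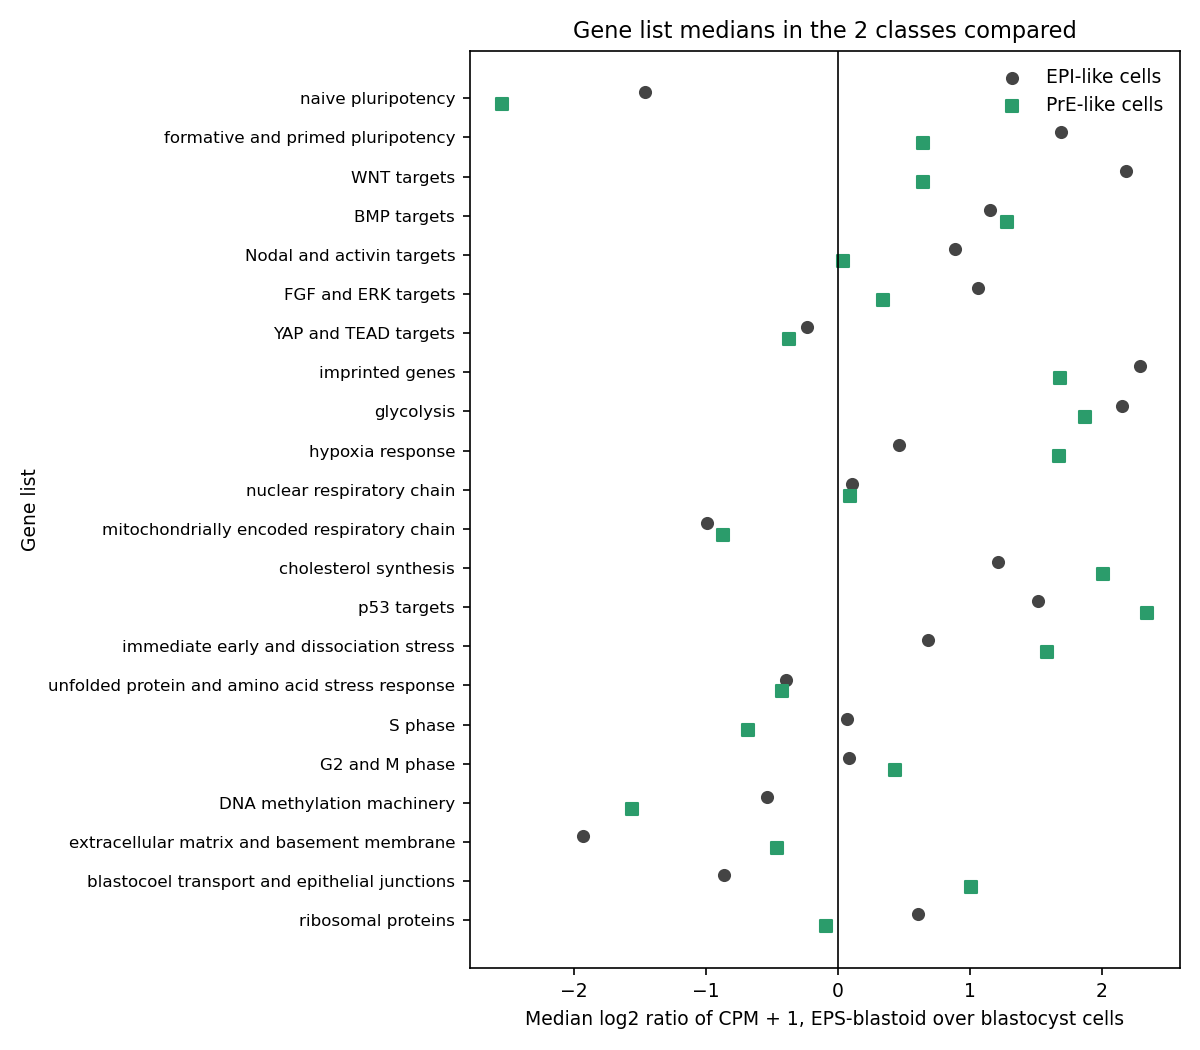
Median log2 ratio (blastoid over blastocyst, 1 CPM added) of 22 of the 28 gene lists in EPI-like cells (circles) and PrE-like cells (squares), the 22 picked for drawing after seeing the data. Naive pluripotency lies at -1.46 and -2.55, and glycolysis at 2.15 and 1.87.

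PrE-like cells were compared next. Both libraries' cells held the endoderm factors, but the blastoid ones were lower in pluripotency genes and higher in the keratins Krt8 and Krt18. Gata6 stood at 99.6 CPM in blastoids against 467 in blastocysts (4.69-fold lower, 4.41 to 4.99), Gata4 at 63.9 against 119 and Pdgfra at 106 against 216, while Sox17 was 1.91-fold higher (1.74 to 2.11). Pou5f1 stood at 21.3 CPM in blastoids against 814 in blastocysts (38.3-fold lower, 35.1 to 41.8), and Nanog at 0.400 against 15.2. All 11 measured naive pluripotency genes were at least 2-fold lower (median log2 -2.55, percentile 0; -3.65 at the floor). Krt18 stood at 666 against 13.0 CPM (51.1-fold higher, 37.9 to 70.6) and Krt8, its partner keratin, at 463 against 33.4. Cdx2 stood at 27.4 against 0.303 CPM, the latter 1 UMI. The endocytic receptor genes Cubn and Amn and the adaptor Dab2, named after their values were seen, stood at 734, 800 and 1399 CPM against 73.7, 45.2 and 74.3. The classes were clusters 3 and 7 of the blastoids and cluster 4 of the blastocysts (31 cells).

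In PrE-like cells, junction, sterol and BMP target genes were higher and DNA methylation and germline genes lower in blastoids. Of 18 junction and transport genes 10 were at least 2-fold higher and 0 lower (median log2 1.01, percentile 99.96; 1.20 at the floor), with the claudin Cldn6 at 464 against 3.94 CPM and the sodium pump subunit Atp1b1 at 432 against 102. Of 17 cholesterol synthesis genes 16 were higher and 0 lower (2.01, percentile 100), with Dhcr7, which makes cholesterol from its last precursor, 11.9-fold and Cyp51 10.1-fold higher. Of 10 BMP targets 6 were higher and 0 lower (1.28, percentile 99.9; 2.09 at the floor), with Id1 25.5-fold higher. WNT targets were higher in 5 of 13 and lower in 0 (0.65, percentile 95.3), FGF and ERK targets higher in 2 of 11 and lower in 2 (0.34, percentile 79.8), and Nodal and activin targets higher in 3 of 8 and lower in 3 (0.04, percentile 55.7). Tdgf1 stood at 0.867 against 228 CPM. Of 9 DNA methylation genes 6 were lower and 0 higher (-1.56, percentile 0), with Tet2 25.5-fold and Dnmt3l, a cofactor of de novo methylation, 5.69-fold lower. Of 8 germline genes 5 were lower and 1 higher (-2.08, percentile 0.03; -3.06 at the floor), with the meiosis gene Sycp1 at 1.00 against 36.4 CPM.

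Glycolysis, imprinted, p53 target, hypoxia and immediate early lists had median ratios above 0 in PrE-like cells. Glycolysis genes were higher in 10 of 14 and lower in 1 (median log2 1.87, percentile 100), with Slc2a3 at 1268 against 46.7 CPM and Tpi1 at 814 against 44.9. Imprinted genes were higher in 12 of 21 and lower in 3 (1.69, percentile 100; 1.67 at the floor), with Meg3 at 964 against 135 CPM and the growth-restraining RNA H19 at 119 against 1.52. Of 12 p53 targets 8 were higher and 1 lower (2.35, percentile 100; 2.39 at the floor), with Cdkn1a 19.4-fold and Btg2 13.3-fold higher. Of 11 hypoxia genes 6 were higher and 1 lower (1.68, percentile 99.97; 1.77 at the floor), and of 14 immediate early genes 11 were higher and 0 lower (1.58, percentile 100; 1.76 at the floor), with Jun 22.1-fold higher. Genes of mitochondrial DNA were lower in 6 of 13 and higher in 0 (-0.87, percentile 0.05). Of 15 S phase genes 5 were lower and 0 higher (-0.68, percentile 0.535), among them the replication clamp Pcna at 52.5 against 123 CPM, whereas in EPI-like cells 1 of 15 was higher and 0 lower (0.07, percentile 85.5). That difference between classes was not tested. Matrix genes parted, 5 of 12 higher and 4 lower (-0.46, percentile 4.24), with Sparc at 3085 against 1143 CPM and Spp1 at 7.83 against 723.

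Among genes that the naming rule admits, the largest ratios in PrE-like cells were led by Spink1, Apob and Ttr. Spink1 (ENSMUSG00000024503, chromosome 18, 43728082 to 43737557), a trypsin inhibitor, stood at 2242 CPM in blastoids against 0.910 in blastocysts (3 UMIs), and Apob, the main protein of lipoproteins, at 468 against 0.303 (1 UMI). Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), a thyroid hormone carrier, stood at 777 against 0 (at least 854-fold higher). Bex1 was 638-fold (310 to 1587) and the protease Ctsh 580-fold higher (249 to 1787), and Clic6, S100a1 and Morc4 stood at 224, 340 and 124 CPM against 0.303, 0.606 and 0.303. Among the lowest were Khdc3 at 0.0667 against 956 CPM, Bhmt at 0.0333 against 247, Calcoco2 (2060-fold, 1371 to 3252) and Dppa3, which guards the egg's DNA methylation, at 0.867 against 1228 CPM. Crxos, Olfr1459, Pramel6 and Pramel7 had no UMI in blastoids and were at least 3235-, 2217-, 1510- and 1082-fold lower. Spink1, Apob and Ttr led 1 of the blastoid PrE-like clusters, so their place here follows in part from that cluster's size.

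TE-like cells are described only, as the blastocyst library held 8 of them. The TE regulators Cdx2, Gata3 and Eomes were lower in blastoids, whereas the keratins Krt8 and Krt18 were high in both libraries. Krt8 stood at 2616 CPM in blastoids against 3119 in blastocysts and Krt18 at 3187 against 4727, while the keratin Krt19, named after its values were seen, stood at 102 against 5.28. Cdx2 stood at 19.9 against 426 CPM (21.4-fold lower, 17.7 to 26.1), Gata3, a partner of Cdx2 in trophectoderm, at 16.5 against 827 (50.2-fold lower, 41.5 to 61.1) and Eomes, a trophoblast stem cell factor, at 1.77 against 215 (121-fold lower, 70.2 to 227). Elf5 stood at 0.127 (1 UMI) against 44.9 CPM. Hand1, a factor of trophoblast giant cells and of mesoderm, stood at 60.0 CPM against 0 (at least 15.1-fold higher) and Gata2 was 2.71-fold higher. After thinning, Cdx2 had a UMI in 18.6% of TE-like blastoid cells (12.1 to 26.9%; 28.4% unthinned) and in 8 of 8 blastocyst ones, against 47.3% of PrE-like and 12.3% (6.88 to 19.7%) of EPI-like blastoid cells and 3.66% of EPI-like blastocyst cells. The TE-like blastoid share for Cdx2 thus lay below that of PrE-like cells in the same library, and its interval overlapped that of EPI-like cells. Median depths were 56914 and 89130.5 UMIs. Over 11885 genes the median log2 ratio was 0.37 in this class.

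Gene lists in TE-like cells parted as well. The blastocyst sum holds 757328 UMIs over 8 cells, so its levels of a few CPM, such as those of Cdkn1c and Bex1, rest on a few UMIs. Of 10 polar TE genes 6 were at least 2-fold lower in blastoids and 2 higher (median log2 -3.89, percentile 0; -4.00 at the floor), the higher ones being Ascl2 and Rhox5. Of 10 mural and giant cell genes 6 were higher and 2 lower (2.07, percentile 100; 1.70 at the floor), with Cdkn1c, an imprinted brake on the cell cycle, at 901 against 3.96 CPM. Of 19 junction and blastocoel transport genes 10 were lower and 2 higher (-1.23, percentile 0), with Aqp3 at 0.887 against 176 CPM and the sodium pump subunits Atp1a1 and Atp1b1 4.54- and 5.04-fold lower. Of 22 imprinted genes 14 were higher and 0 lower (3.15, percentile 100; 2.54 at the floor), with H19 at 512 CPM against 0 (at least 129-fold higher) and Phlda2 at 1474 against 7.92 (186-fold, 85.5 to 507). Glycolysis genes were higher in 12 of 14 and lower in 1 (2.80, percentile 100; 2.37 at the floor), with Ldha 176-fold higher (68.7 to 646). WNT targets were higher in 10 of 12 and lower in 0 (3.67, percentile 100; 1.99 at the floor), and so were immediate early genes, which dissociation can turn on, in 12 of 14 and 0 (3.48, percentile 100; 2.33 at the floor). Higher and lower were 7 and 1 of 12 matrix genes (3.01, percentile 100; 2.65 at the floor), 6 and 1 of 10 BMP targets (2.44, percentile 99.98; 1.61 at the floor), 9 and 1 of 12 p53 targets (1.58, percentile 100; 1.66 at the floor) and 8 and 0 of 15 G2 and M phase genes (1.04, percentile 99.98). Among genes that the naming rule admits, the largest ratios were led by Bex1 at 2289 against 2.64 CPM. At the other end Crxos, BC053393 and Timd2 had no UMI in blastoids (at least 4489-, 2944- and 1069-fold lower), and AA467197 stood at 2.54 against 3009 CPM and Dppa1 at 1.01 against 1134.

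A further question was whether lineage genes part the classes of blastoids by as much as those of blastocysts. The clusters were named by these same marker lists, so that the markers part the classes at all follows in part from the naming. Only the sizes are set side by side. PrE markers parted the classes by more in blastoids: their median log2 ratio of PrE-like over EPI-like cells was 5.70 in blastoids and 2.69 in blastocysts, at least 2-fold for 16 of 16 in both. EPI markers parted the same classes by -4.48 in blastoids, at least 2-fold for 16 of 16, and by -1.49 in blastocysts, at least 2-fold for 10 of 16. TE markers parted TE-like from EPI-like cells by less in blastoids, 2.66 with 10 of 13 at least 2-fold higher in TE-like cells against 4.82 with 13 of 13. EPI markers parted TE-like from EPI-like cells by -4.31 in blastoids and -4.05 in blastocysts. The first values hold Gata6 and other PrE markers that the EPI-like blastocyst cells also expressed.

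Over all kept cells the ratios, given here among genes that the naming rule admits, also reflect which classes each library held. Spink1, at 621 against 0.295 CPM, and T, at 107 against 0.148 CPM (2 UMIs), were among the highest, with Apob and Ttr, which mark 1 blastoid cluster. Bex1 was 450-fold (322 to 650), the heparan sulphate proteoglycan Gpc3 172-fold (96.1 to 345), Ldhb 133-fold and Bex4 125-fold higher in blastoids. Lowest were Pramel6, Pramel4, Khdc3, Sycn, Bhmt, Crxos and Olfr1459, and Fbp2, a fructose bisphosphatase, which was 584-fold lower (476 to 725).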

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

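All 3 tests on TE-like cells in this part were chosen after the result was seen. UMIs outside the kept cells were not used in the comparisons: they made up 23.3% of all UMIs in the blastoid library and 33.1% in the blastocyst library. Barcodes under 100 UMIs held only part of these: 1414448 of 145763691 UMIs in the blastoid library and 3440793 of 20255613 in the blastocyst library. The rest lay in larger barcodes that were not kept. Lineage transcripts in the barcodes under 100 UMIs lay above what a count of 0 allows. In blastoid barcodes under 100 UMIs, which hold RNA but no cell, Pdgfra, a receptor of primitive endoderm, stood at 48.1 CPM against 30.6 in the kept cells. In blastocyst barcodes under 100 UMIs, Cdx2, the TE regulator, stood at 45.9 CPM (39.0 to 53.7) against 25.7 in the kept cells, and Krt18 at 523 against 293.

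The Cdx2 value bears on a pattern in the blastocyst library, which held 8 TE-like cells of 126 although trophectoderm is the outer layer of a blastocyst. The mitochondrial limit as the cause could be settled only for cells rich in keratin. The TE-like share was 7.52% with the limit at 30%, inside the interval of 2.78 to 12.1% at 15%. That limit passed 141 of 165 called barcodes against 135, too few more to move the share far. Of the 30 barcodes over 15%, 1 (3.33%, 0.0844 to 17.2%) reached 0.5 of the median keratin level of TE-like cells, against 7.14% of the kept cells. Over all 165 called barcodes, with no limit, 10 reached it (6.06%, 2.94 to 10.9%). This argues against the limit as the cause for cells that rich in keratin, but not for TE cells with less. As to TE-like cells hidden in other clusters, 1 kept cell outside the TE-like cluster reached 0.5 of its median keratin level. Few cells as rich in keratin thus lay elsewhere. The cut came from the 8 TE-like cells themselves, so TE cells with less keratin would be missed. At resolution 0.5 a cluster with 23.8% of the cells took the TE-like name, and hidden TE-like cells stay open. A candidate explanation is that TE cells broke before capture, since the TE-like profile was fitted to 11.8% of the UMIs in barcodes under 100 UMIs and to 5.59% in the kept cells. Relative to the kept cells, those barcodes had a median log2 ratio of 0.58 over 14 TE markers and -0.32 over 16 EPI markers. A lower share of TE in the blastocysts loaded was not tested and stays open.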

How the results depend on the processing

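Chosen only after the data were seen were doublets by expected share, the EPI-like cluster with the most markers alone, the 40% naming minimum, naming without a margin, naming whatever other markers lead, thinned joint clustering and TE-like cells under a minimum of 5. No paired analysis was possible because each group holds 1 library. Of the main results (cell numbers, class shares, mixed clusters, correlations, selected shares of cells with a UMI, and lists at either end of the percentile range), 395 values under an alternative stayed within tolerance, 74 moved and 5 turned sign. Of 1000 other gene values 664 stayed, 334 moved and 2 turned sign, and of 949 other list medians 839 stayed, 107 moved and 3 turned sign. Median-ratio scaling and leaving out mitochondrial and ribosomal protein genes moved none of the main results beyond tolerance, and gene minimums of 500 and 2000 removed no cell and so test nothing. The 8 TE-like blastocyst cells and the 126 blastocyst cells in all limit every share and low level from that library. Where no reason is given below, the cause was not tested.

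At a mitochondrial limit of 10%, 45 blastocyst cells were kept, the TE-like blastocyst share was 0% and the EPI-like blastoid share 4.13%. The EPI-like blastoid share was 3.94% at a calling threshold of 20% and 7.48% with 1000 variable genes. At a threshold of 5%, the PrE-like and unnamed blastocyst shares were 16.3% and 17.0% and the streak-like share 20.3%. With doublets kept, blastoid shares were 3.79% EPI-like, 18.7% streak-like and 47.2% unnamed, the EPI-like Nodal median was 0.20 and the PrE-like naive median -3.17. With doublets by expected share, the streak-like share was 24.7%, the unnamed blastoid share 38.7%, and these medians 0.14 and -3.17.

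At resolution 0.5, blastoid shares were 8.28% EPI-like, 10.5% TE-like, 20.2% streak-like and 37.3% unnamed, and blastocyst shares 57.1% EPI-like and 23.8% TE-like. At resolution 2, the TE-like blastoid share was 3.61%, and 14.3% of blastocyst cells were PrE-like and 14.3% unnamed. At the 40% naming minimum, 8.08% of blastoid cells were streak-like and 55.3% unnamed, and 37.4% were unnamed with no margin and 33.8% with naming whatever other markers lead. These follow from the rule itself. With the libraries clustered together, EPI-like shares were 4.11% in blastoids and 81.7% in blastocysts, the PrE-like blastocyst share 11.1% and the unnamed blastoid share 43.5%. EPI-like medians were then -0.093 for Nodal targets, which turned sign, and 0.35 for FGF and ERK targets, and PrE-like medians -1.79 for naive, 0.94 for hypoxia and 1.41 for cholesterol genes. After anchor integration, 12.7% of blastocyst cells were PrE-like and 16.7% unnamed, and mixed clusters held 41.9% of blastoid and 59.5% of blastocyst cells, by the construction of the method.

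With only genes at 20 CPM or more, Spearman correlations were 0.757 for EPI-like, 0.684 for PrE-like and 0.655 for TE-like pairs. EPI-like medians were 2.87 for WNT targets and 1.38 for immediate early genes, and turned sign to -0.24 for Nodal targets, -0.42 for hypoxia and -1.15 for mural TE genes. PrE-like medians were 2.77 for BMP targets, 2.31 for mural TE and -4.22 for germline genes and turned to 0.022 for lineage regulators, and the TE-like median of PrE markers turned from 3.08 to -0.22. Fewer genes enter these lists by construction. With 10 CPM added, which pulls in ratios of weak genes by construction, EPI-like medians were 0.87 for WNT, 0.31 for BMP and 0.14 for Nodal targets and 0.79 for imprinted genes. PrE-like medians were then 0.43 for BMP targets, 0.24 for mural TE, 0.71 for hypoxia, 0.64 for immediate early, 1.06 for imprinted, 1.70 for p53 target, -1.27 for naive, -0.64 for germline and -0.62 for sex-linked genes.

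With thinned cells the EPI-like Nodal median turned to -0.41. Unthinned, a Gata6 UMI was found in 69.0% of EPI-like blastocyst and 5.69% of EPI-like blastoid cells, and a Cdx2 UMI in 92.1% of streak-like and 28.4% of TE-like blastoid cells. Counting 2 or more UMIs, these shares in blastoids were 0% for Gata6, and 76.3% and 11.02% for Cdx2. With the EPI-like cluster with the most markers alone, medians were 0.31 for FGF and ERK targets, 1.70 for imprinted and 0.050 for mural TE genes, and 14.8% of its thinned blastocyst cells had a Gata6 UMI. Definitive endoderm markers turned from -1.54 to 0.67, Gata4 to 0.10 and Sox17 to 1.69.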

Other observations

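Of the tests in this part, the free RNA bound, the left-out gene groups and the spread of mitochondrial genes were chosen after the result was seen, and thinned joint clustering was added after seeing the data, with its prediction written before its own result. Lists not described above are given here for EPI-like and PrE-like cells. Of 16 ribosomal protein genes 2 were at least 2-fold higher in blastoids and 0 lower (median log2 0.61, percentile 99.7), with Rplp0 at 7610 against 3646 CPM, while in PrE-like cells 0 of 16 were higher or lower (-0.09, percentile 38.3). Of 10 germline genes 2 were higher and 4 lower in EPI-like cells (-0.46, percentile 21.6), with the meiosis genes Sycp3 at 13.4 against 42.9 CPM and Sycp1 at 4.10 against 23.2. Of 3 measured maternal transcripts 1 was higher and 1 lower (-0.64, percentile 15.3): Dppa3 stood at 272 against 1996 CPM and Zp3, a coat protein of the egg, at 29.8 against 2.85. Amino acid stress genes parted, 2 of 14 higher and 1 lower (-0.40, percentile 15.8): Asns, which makes asparagine, stood at 577 against 124 CPM and Phgdh, which starts serine synthesis, at 230 against 79.0, and Chac1 was lower. In PrE-like cells Asns went the other way, at 130 against 505 CPM, in a list with 2 of 14 higher and 4 lower (-0.42, percentile 5.85).

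YAP and TEAD targets showed little common direction, with 2 of 9 higher and 3 lower in EPI-like cells (-0.23, percentile 46.9) and 2 of 9 higher and 1 lower in PrE-like cells (-0.37, percentile 11.8), and Tead4, a TE activator, stood at 3.23 against 30.2 CPM in EPI-like cells. G2 and M phase genes were higher in 3 of 15 and lower in 0 of them in EPI-like cells (0.09, percentile 76.2), with Cdc20, an activator of mitotic exit, at 238 against 78.6 CPM, and higher in 2 of 15 in PrE-like cells (0.44, percentile 96.9). Polar TE genes were higher in 3 of 9 and lower in 4 in EPI-like cells (-0.54, percentile 12.7), and higher in 2 of 10 and lower in 5 in PrE-like cells (-0.48, percentile 6.45), with the FGF receptor Fgfr2 at 11.4 against 71.3 CPM in the latter. Mural TE and giant cell genes were higher in 3 of 9 and 4 of 10 and lower in 2 and 1 (0.80, percentile 98.7, and 1.07, percentile 99.7), but the EPI-like median turned to -1.15 with genes under 20 CPM left out and was 0.050 against the blastocyst cluster with the most EPI-like markers alone. The protease Ctsl stood at 246 against 549 CPM in EPI-like and 5545 against 1212 in PrE-like cells. Formative genes in PrE-like cells were higher in 4 of 9 and lower in 2 (0.65, percentile 92.8), with Dnmt3b at 123 against 364 CPM. Of 6 sex-linked genes 3 in EPI-like and 4 in PrE-like cells were lower in blastoids and 0 higher (-0.83, percentile 6.51, and -1.25, percentile 0.51). Xist, transcribed from the silenced X of female cells, stood at 1.12 against 366 CPM in EPI-like cells, with blastoids labelled male and blastocysts pooled male and female. The only X-linked members of the list are Xist and Tsix, so Y-linked genes were among the lower ones in both classes. The labelled sexes would not place Y-linked genes lower in blastoids, so they do not account for the whole list.

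Blastoid cells had a lower mitochondrial share than blastocyst cells, a median of 6.33% against 10.3% of UMIs. Cell depth as its cause is argued against by cells of matched UMIs, where the gap was 4.21 percentage points (6.23% in 144 blastoid and 10.4% in 62 blastocyst cells). A single factor on all mitochondrial transcripts, as leaking cells might give, is argued against by log2 ratios of mitochondrial genes that ranged over 2.15 in EPI-like cells. Culture, strain and stage differ between the libraries as the design has them, were not tested and stay open.

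No uncorrected joint cluster was mixed, and 3 technical explanations for this were tested. Depth as the whole cause is argued against by thinned cells, of which 0% of blastocyst cells lay in mixed clusters, and sex-linked, cell cycle, mitochondrial and ribosomal genes by the same 0% with these left out. Free RNA was tested in the blastoid library only. For genes at least 2-fold higher in EPI-like blastoid cells it is argued against by their median level, 21.6 times the most that free RNA allows. That bound was taken from T in PrE-like blastoid cells, at 4.31% of its level in barcodes under 100 UMIs. Genes higher in blastocyst cells were not set against the free RNA of that library, which stays open. Barcodes under 100 UMIs held 3440793 of 20255613 UMIs in the blastocyst library and 1414448 of 145763691 in the blastoid library. With 1 library each, a difference between library preparations, strains, stages, culture or the structures themselves may account for the lack of mixed clusters, and these cannot be told apart.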
